A study of Mus musculus with 16 samples.

How the data were processed

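Whole bone marrow RNA was sequenced from mice of 2 genotypes, C57BL/6 wild type (WT) and Nrf2-/- (KO), under 4 treatments with 2 libraries per group, which gives 16 libraries in 8 groups. The treatments were PBS (the vehicle control), BMX-001 (which the labels describe as a radioprotector), 5-fluorouracil (5-FU, a thymidylate synthase inhibitor used in chemotherapy) and both drugs. BMX-001 was given at 0.5 mg/kg, first 24 h before 5-FU and then every 3 days. 5-FU was given at 20 mg/kg with a second dose on day 7, and marrow was taken on day 10. The WT animals were males of 8 to 10 weeks. No age was given for the KO animals in the labels used here, so the genotypes are not known to be matched in age. Per the labels the marrow was isolated in duplicate, and they do not say whether the duplicates are different animals. If they are not, the p-values given here measure only the spread between these samples, which may be technical.

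The authors deposited raw counts per Ensembl gene for 57132 genes, with 1 column per library, and 0 columns were left unused. Per the labels the submitters' processing notes name Trim Galore 0.6.4, FastQC 0.12.1, Salmon 1.4.0, featureCounts, DESeq2 1.38.3, R 4.3.0 and the build GRCm39, without saying which tool made which value. The aligner, the annotation release and the strand setting are not given in the sources used here. The values were whole numbers with library totals of 27305707 to 39909188 counts. Symbols were joined by Ensembl gene ID from a mouse annotation of an earlier build, so no coordinates are given, and that annotation served for names, neighbour order, GC content and length only. A symbol was found for 51880 of the 57132 IDs, and IDs without one held 2.69% of all counts and 925 of the genes tested.

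Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8). Genes with low counts were removed with filterByExpr, which left 19152 genes. Library sizes were scaled with TMM factors, and 8 group means were fitted with edgeR's robust quasi-likelihood model, which leaves 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The 13 comparisons were KO against WT averaged over treatments and in PBS, each drug and their combination against PBS in each genotype, the combination against 5-FU in each genotype, and 3 interactions of genotype with treatment. Log2 fold changes are given with their standard error (SE) from this fit. Expression levels are normalised CPM (counts scaled to the same total in each library), given as mean ± SD with the number of libraries. All adjusted p-values of single genes come from edgeR unless DESeq2 is named.

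Before the data were examined, 28 gene lists were fixed for marrow cell types, for stress and drug responses and for sex-linked transcripts. Of the 748 symbols in them 746 were matched. All but the sex-linked list, which served as a check of the libraries, were tested with camera, a test of whether a list's genes rank above or below other genes, with a preset correlation of 0.01 between genes and, as the alternative, with the correlation estimated from the residuals. Adjusted p-values of lists were corrected over the 27 lists of a comparison. Beside the number of list members called over all genes stands the number called when the correction is adjusted over the list alone. With an estimated correlation no list passed the threshold in any of the 13 comparisons, and the smallest adjusted p of a list was 0.131. A list said to have risen or fallen passed the test with the preset correlation only.

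The rule for named genes was also fixed before the data were examined. It takes Nfe2l2 in every comparison. It takes the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted, immunoglobulin, T cell receptor and pseudogene names. It takes up to 3 called members of each list that passed camera, or the highest-expressed members where none was called. Where fewer than 4 genes met the conditions for the 5 highest and 5 lowest, it takes the 5 genes of smallest unadjusted p, whatever their names. For interactions it takes 3 genes. The rule of smallest p applied to KO against WT in PBS, where 5 genes were called, immunoglobulin names among them. The same rule was applied to a fit without KO BMX-001 replicate 1, referred to as the 15-library fit, which tested 19694 genes. That fit was added after seeing the data, because this library stood far from the others.

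Spread between the 2 libraries of a group exceeded sampling noise in all 8 groups, with a chi-square per degree of freedom of 8.39 to 137. Tests were tried on counts simulated from each gene's mean over the libraries, the library sizes and the estimated spread between libraries. In them 100 genes were changed 1.5-fold and 100 genes 2-fold, all with a mean of at least 1 CPM, and erythroid genes were lowered. Real differences between groups and the profile of KO BMX-001 replicate 1 were not reproduced, so the shares hold for such simulated counts. For 5-FU in WT the fit recovered 11% of genes changed 1.5-fold and 58% of genes changed 2-fold, and the 15-library fit recovered 48% and 66%. For genotype the shares were 71% and 93%, and 88% and 94% in the 15-library fit. Between 4 and 13 unchanged genes were called per simulation. Xist had 1 to 10 counts and the Y-linked gene Ddx3y 1335 to 2125 counts in all 16 libraries, as in male mice. The SEs given here include the spread between libraries that the fit estimated, and the SDs are spreads between libraries.

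The alternatives tried were the DESeq2 Wald test with its size factors, RLE scaling in edgeR, no filter on low counts, a fit of the compared groups only, removal of 12 haemoglobin genes, a term for the replicate number, and leaving out each library in turn. Leaving out a library of a pair leaves a lone sample, which is then assumed to vary like the other groups. Alternatives chosen after seeing the data were the 15-library fit, that fit with another library left out, and that fit with each library's trend over GC content and transcript length removed.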

Results

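The data were 16 RNA sequencing libraries of mouse bone marrow, 2 for each of 4 treatments in WT and in KO (Nrf2-/-) mice. Total counts ran from 34387432 to 39909188 in the 8 WT libraries and from 27305707 to 36588168 in the 8 KO libraries. Haemoglobin transcripts made up 3.86% to 8.02% of counts and mitochondrial transcripts 0.55% to 1.15%. Nfe2l2 (ENSMUSG00000015839.7), the gene for NRF2 and the target of the knockout, stood at 116 ± 6.18 CPM in WT (SD, n = 8) and 8.97 ± 3.32 CPM in KO (SD, n = 8), and its lowest WT value of 102 CPM lay far above its highest KO value of 16.7 CPM. KO BMX-001 replicate 1 stood apart from all other libraries. It lay at 111.9 on the first principal component, which held 30.9% of the variance, while the other libraries lay between -31 and 7.6. It had 12210 CPM of the nuclear RNA Malat1 against 2549 to 5345 CPM elsewhere, and 283.5 CPM of the granule enzyme gene Mpo against 1385 to 2272 CPM elsewhere.

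The comparison of KO with WT marrow over the 4 treatments asked which transcripts depend on NRF2, the transcription factor that drives antioxidant and detoxification genes. Nfe2l2 fell by 3.74 ± 0.12 on the log2 scale (SE, adjusted p = 2.68e-09). Known NRF2 targets fell with it. Srxn1, which repairs oxidised peroxiredoxins, had a log2 fold change of -1.09 ± 0.11 (adjusted p = 0.000587), Nqo1, a quinone reductase, -0.63 ± 0.07 (adjusted p = 0.00117), and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, -0.37 ± 0.06 (adjusted p = 0.0179). Pir, which encodes the iron-binding protein pirin, changed by -1.42 ± 0.09 (adjusted p = 4.11e-06). Levels of Srxn1 were 8.49 ± 2.18 CPM in KO and 17.9 ± 3.34 CPM in WT (SD, n = 8 each), and those of Nqo1 12.2 ± 1.34 and 18.9 ± 1.55 CPM. Of the 33 NRF2 targets tested, 4 fell, 9 fell adjusted over the list alone, and none rose. The list passed camera (median log2 fold change -0.13, adjusted p = 4.22e-12; adjusted p = 0.157 with an estimated correlation). Its median was -0.242 without KO BMX-001 replicate 2, which leaves replicate 1 alone in its group. Without WT BMX-001 with 5-FU replicate 1 it was -0.099. Among other antioxidant genes Cat, which encodes catalase, fell by 0.78 ± 0.06 on the log2 scale (adjusted p = 5.8e-05).

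**Figure D1:**
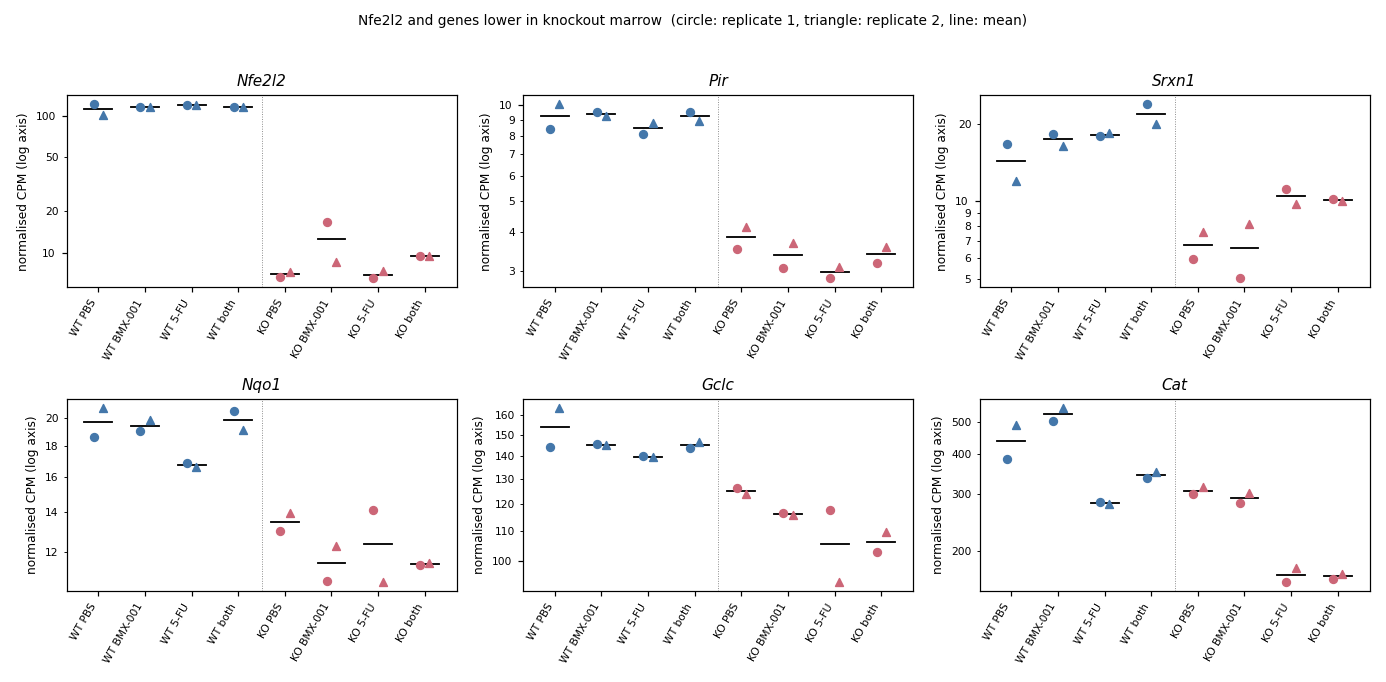
Normalised CPM on a log axis for Nfe2l2 and 5 genes called lower in KO marrow, in the 8 groups; circles are replicate 1, triangles replicate 2 and lines the group means, with WT in blue and KO in red. Nfe2l2 lies between 102 and 122 CPM in the WT libraries and between 6.48 and 16.7 CPM in the KO libraries, and Pir, Srxn1 and Nqo1 separate the genotypes in every library.

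Immune cell transcripts also differed between the WT and KO groups, which are not known to be matched in age. Marco, a scavenger receptor of macrophages, fell by 3.78 ± 0.42 on the log2 scale from a level of only 1.08 ± 0.439 CPM in WT (SD, n = 8; adjusted p = 0.00244), and Cd5l, a secreted macrophage protein, by 0.85 ± 0.14 (adjusted p = 0.0446). Together 2 of 24 macrophage genes fell, 3 adjusted over the list alone, with adjusted p = 0.38 for the list with an estimated correlation. Igha, the constant region of IgA, rose by 2.83 ± 0.28 (adjusted p = 0.00286), to 931 ± 635 CPM in KO from 115 ± 28.8 CPM in WT (SD, n = 8 each), and the light chain segment Iglv1 by 0.82 ± 0.13 (adjusted p = 0.0303). These were the 2 of 20 plasma cell genes that rose, with 5 higher and 3 lower adjusted over the list alone and adjusted p = 0.373 with an estimated correlation. Iglv1 was not higher in every KO group. It stood at 132.7 ± 34.8 CPM in KO PBS and 76.1 ± 7.06 CPM in KO 5-FU (SD, n = 2 each). In KO it was 35.3 ± 1.19 CPM with BMX-001 and 30.2 ± 10.6 CPM with both drugs (SD, n = 2 each). Its WT level was 32.8 ± 6.3 CPM (SD, n = 8). B lineage genes lay lower, with a median of -0.32 and no called member of 28, but 17 lower adjusted over the list alone. B cell precursor genes had a median of -0.34 with 1 called member of 24, Myl4 (-0.81 ± 0.14, adjusted p = 0.0341), and 15 lower adjusted over the list alone. Both lists passed camera, each with adjusted p = 0.157 with an estimated correlation. Dynlt1b, a dynein light chain gene, rose by 1.04 ± 0.10 (adjusted p = 0.000587). All 36 cell cycle genes had negative log2 fold changes with a median of -0.14, with no member called over all genes or adjusted over the list alone (adjusted p = 6.64e-09 in camera; adjusted p = 0.404 with an estimated correlation). This median moves with the deviating library. It was -0.072 without KO BMX-001 replicate 1 and -0.245 without replicate 2.

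In all, 34 genes differed between the genotypes, 12 higher and 22 lower in KO, at an adjusted p under 0.05 in edgeR. DESeq2 called 347. The count was 273 (122 higher, 151 lower) in the 15-library fit and 4467 without KO BMX-001 replicate 2, which leaves the deviating library alone in its group. It was 60 without KO 5-FU replicate 2, lay within 1.5 times of 34 without WT PBS replicate 1 or either KO PBS library, and was between 14 and 22 without any other library, with 14 without WT PBS replicate 2. Nfe2l2, Pir, Srxn1, Nqo1, Cat, Marco, Dynlt1b and Igha were called whichever library was left out, while Gclc, Cd5l, Myl4, Iglv1 and Tanc1 (0.73 with all libraries) were each lost without at least 10 of the 16 libraries, with their largest adjusted p between 0.0875 and 0.144. Genes called in the 15-library fit included the dendritic cell receptor Ly75 (0.53 ± 0.05), the progenitor cytokine receptor Flt3 (0.35 ± 0.06), Ftl1, the ferritin light chain (-0.29 ± 0.05), and Hspa5, an endoplasmic reticulum chaperone (-0.38 ± 0.07). Ly75 is among the 200 tested genes nearest to Nfe2l2, where called genes were more frequent.

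In PBS alone, where the genotypes were compared without any drug, Nfe2l2 stood at 6.95 ± 0.367 CPM in KO and 112 ± 13.9 CPM in WT (SD, n = 2 each). It fell by 4.01 ± 0.23 on the log2 scale (adjusted p = 7.58e-06) and Pir by 1.27 ± 0.17 (adjusted p = 0.0238). The immunoglobulin segments Ighv1-15 (4.09 ± 0.45), Ighv14-2 (3.21 ± 0.39) and Iglv1 (1.93 ± 0.26) rose, with adjusted p-values of 0.00736, 0.0134 and 0.0297. Ighv1-15 reached 36.7 ± 16.6 CPM in KO against 2.15 ± 0.964 CPM in WT (SD, n = 2 each). NRF2 targets had a median of -0.06 with no member called, 3 lower adjusted over the list alone, and adjusted p = 0.597 with an estimated correlation. The B lineage list had a median of -0.45, with no member called either way (adjusted p = 0.512 with an estimated correlation). These 5 genes were the edgeR calls, against 36 in DESeq2 and 20 in the 15-library fit, where Srxn1 was also lower (-1.08 ± 0.16, adjusted p = 0.0156). Among the 4 compared libraries the count was 3 without WT PBS replicate 1 or 2. Nfe2l2 alone was called whichever of the 4 was left out; Pir was lost without any of the 4 (largest adjusted p 0.201), Ighv14-2 without either WT PBS library (0.255), Ighv1-15 without WT PBS replicate 2 (0.135), and Iglv1 without WT PBS replicate 2 or KO PBS replicate 1 (0.201).

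The effect of 5-FU in KO marrow, 3 days after its second dose, was a fall in genes of late red cell maturation. Tmcc2, an erythroid membrane protein gene, fell by 1.13 ± 0.15 on the log2 scale (adjusted p = 0.0124), Xpo7, an exportin needed in terminal erythroid maturation, by 1.22 ± 0.18 (adjusted p = 0.0133), and Epb42, which encodes a membrane skeleton protein of red cells, by 0.80 ± 0.12 (adjusted p = 0.0133). Tmcc2 went from 1425 ± 161 CPM in PBS to 653 ± 81.8 CPM after 5-FU, and Epb42 from 532 ± 36.3 to 306 ± 17.6 CPM (SD, n = 2 each). In the heme and iron list Slc25a37, the mitochondrial iron importer (-0.90 ± 0.14, adjusted p = 0.0178), and Fech, the last enzyme of heme synthesis (-0.69 ± 0.14, adjusted p = 0.0478), fell as well. Of 35 erythroid genes 8 fell, 20 adjusted over the list alone, and none rose, with a median of -0.42 (adjusted p = 1.79e-38 in camera; adjusted p = 0.131 with an estimated correlation). Of 26 heme and iron genes 2 fell, 7 adjusted over the list alone, with adjusted p = 0.333 with an estimated correlation.

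Other gene groups moved in KO marrow too. Cat fell by 0.87 ± 0.12 on the log2 scale (adjusted p = 0.0133) and Ucp2, an uncoupling protein of mitochondria, by 0.72 ± 0.14 (adjusted p = 0.0489), the 2 called members of 22 other antioxidant genes (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.333 with an estimated correlation). Rsad2, the interferon-induced viperin gene, fell by 1.23 ± 0.18 (adjusted p = 0.0133), the 1 of 32 interferon response genes called (8 lower adjusted over the list alone, adjusted p = 0.333 with an estimated correlation). Specc1 (-1.21 ± 0.15), Arhgef37 (-1.36 ± 0.25) and Aldh3b2 (-1.18 ± 0.23) completed the lowest 5, and Cd200, a ligand that restrains myeloid cells, rose by 0.91 ± 0.17 (adjusted p = 0.0413). Monocyte genes had a median of -0.37, with no call of 24 and 5 lower adjusted over the list alone (adjusted p = 0.333 with an estimated correlation). In the 15-library fit Cx3cr1 (-0.90 ± 0.10) and Csf1r (-0.64 ± 0.10), receptors of monocytes, fell. Targets of p53 rose as a list by a median of 0.26, with no call of 28 and 2 higher adjusted over the list alone (adjusted p = 0.00135 in camera, but 0.084 without KO 5-FU replicate 1; adjusted p = 0.131 with an estimated correlation), and in the 15-library fit the p53 target Eda2r rose by 2.37 ± 0.42 (adjusted p = 0.00471). Stromal and osteolineage genes had a median of 0.91, 31 of 32 of them positive, with no member called either way (adjusted p = 0.333 with an estimated correlation), and megakaryocyte genes one of 0.96, also with no member called either way (adjusted p = 0.618 with an estimated correlation).

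In total 87 genes changed after 5-FU in KO, 2 higher and 85 lower, and DESeq2 called 379. The count was 200 with only the 2 groups in the fit and 556 (83 higher, 473 lower) in the 15-library fit. It rested on each of the 4 compared libraries, with 37 without KO PBS replicate 1, 2 without KO 5-FU replicate 1, and 0 without KO PBS replicate 2 or KO 5-FU replicate 2. Each named gene of this comparison lost its call without at least 3 of these 4 libraries, with adjusted p-values up to 0.37, and kept its sign.

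In WT marrow haemoglobin and monocyte transcripts stood lower after the same treatment, but with all 16 libraries the 1 gene called was Zfp958, a zinc finger gene, which rose by 1.01 ± 0.13 on the log2 scale (adjusted p = 0.043). Hba-a1, an alpha globin gene, stood at 7657 ± 592 CPM after 5-FU and 12530 ± 1820 CPM in PBS (SD, n = 2 each), a log2 fold change of -0.71 ± 0.16 (adjusted p = 0.0889). Zfp120, Ptprcap, G2e3 and Gm42463 followed by p, with log2 fold changes of 0.85 ± 0.12, -0.73 ± 0.11, 0.65 ± 0.10 and 3.19 ± 0.49, each with adjusted p = 0.0696. The erythroid list passed camera with a median of -0.10, no call of 35 and 9 lower adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). The monocyte list did so with a median of -0.27, no call of 24 and 2 lower adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). Other antioxidant genes had a median of -0.23 with 6 of 22 lower adjusted over the list alone (adjusted p = 0.539 with an estimated correlation), and immediate early genes a median of -0.67 with 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). In WT PBS replicate 2 the immediate early gene Fos stood at 300.6 CPM against 38.1 CPM in replicate 1, which moves with that list: without WT PBS replicate 2 its median was -0.21 and its adjusted p in camera 0.148.

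The 15-library fit called 1353 genes in WT, 616 higher and 737 lower. Cat (-0.64 ± 0.10), Hba-a1 (-0.71 ± 0.13), Alas2, the rate-limiting enzyme of heme synthesis in red cells (-0.62 ± 0.12), the monocyte receptor Cx3cr1 (-0.70 ± 0.10), the chemokine gene Ccl9 (-0.75 ± 0.13) and the transcription factor gene Jund (-1.21 ± 0.28) were lower, and the complement receptor gene Cr2 was higher (1.07 ± 0.14). DESeq2 on all 16 libraries called 474. In the 16-library fit the count was 46 without WT PBS replicate 1, 2 without WT PBS replicate 2 and 0 without WT 5-FU replicate 1 or 2, and Zfp958 was also lost without WT PBS replicate 2. Without KO BMX-001 replicate 1 and a further library it was 1612 without WT PBS replicate 1, 230 without WT PBS replicate 2, 164 without WT 5-FU replicate 1 and 9 without WT 5-FU replicate 2. With GC content and length trends removed from the 15-library fit, 199 genes were called. Without that removal, the 15-library fit had 166 genes lower after 5-FU in both genotypes, where 17.7 would be shared by independent lists, and 14 higher in both against 2.6.

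**Figure D2:**
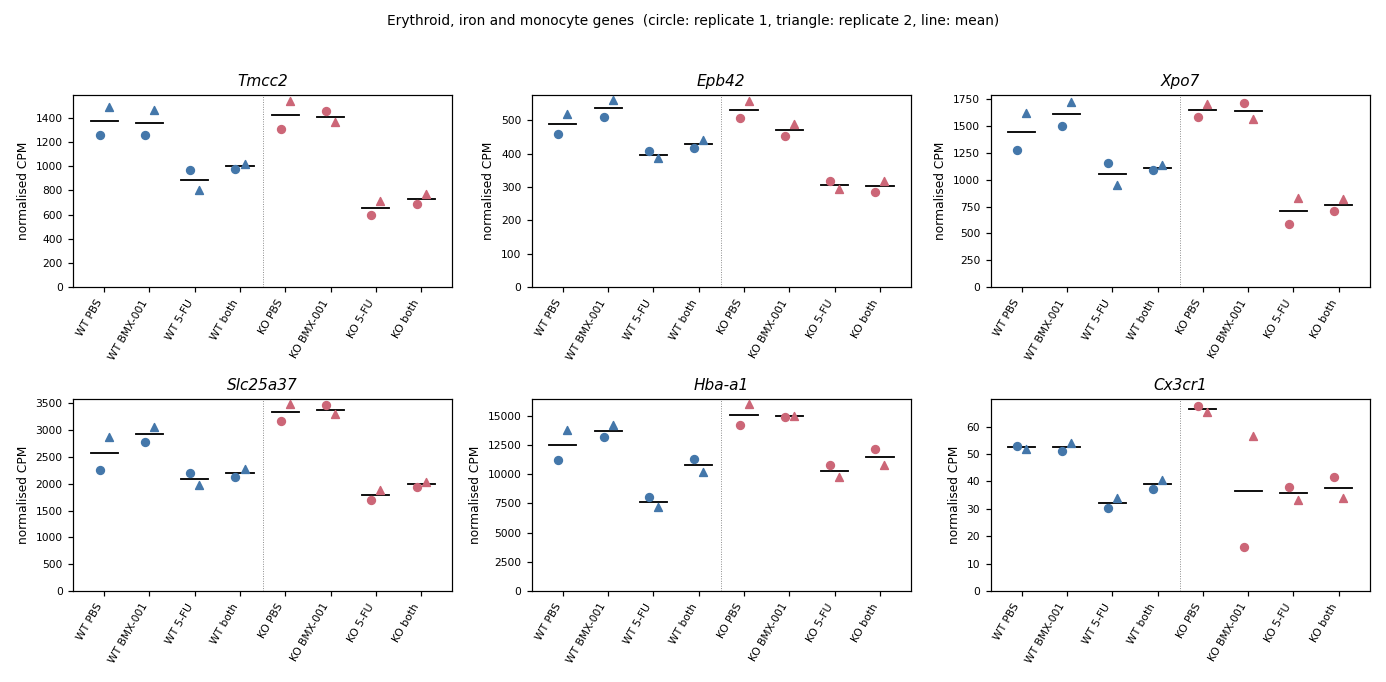
Normalised CPM for 3 erythroid genes (Tmcc2, Epb42, Xpo7), the mitochondrial iron importer Slc25a37, the alpha globin gene Hba-a1 and the monocyte receptor gene Cx3cr1 in the 8 groups, with axes starting at 0; circles are replicate 1, triangles replicate 2 and lines the group means, with WT in blue and KO in red. In KO marrow Tmcc2 averages 1425 CPM in PBS and 653 CPM after 5-FU, and Hba-a1 in WT averages 12530 CPM in PBS and 7657 CPM after 5-FU.

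Whether the genotypes responded differently to 5-FU was asked with an interaction test. No gene passed it in edgeR, with 1090 genes at an unadjusted p under 0.05, 19 called by DESeq2, 0 in the 15-library fit, and 1 without WT PBS replicate 2 or KO PBS replicate 1. The 3 genes of smallest p were Gm42463 (-3.84 ± 0.72), Ptprcap (0.75 ± 0.15) and Parp14, an interferon-induced gene (-0.81 ± 0.17), each with adjusted p = 0.846. The erythroid list had a median of -0.32, more negative in KO, with no call of 35 and 2 lower adjusted over the list alone (adjusted p = 6.7e-10 in camera; adjusted p = 0.655 with an estimated correlation), and of -0.16 without KO 5-FU replicate 2. A larger erythroid fall in KO than in WT was thus not shown once the correlation between these genes was estimated. Across all 19152 genes the 5-FU effects in WT and KO had a Pearson correlation of 0.23 and a Spearman correlation of 0.32, and 0.32 and 0.38 over genes with a mean log2 CPM of at least 3; genes are not independent replicates.

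BMX-001 alone was compared with PBS to ask what it does in undamaged marrow. In WT no gene passed in edgeR, with 977 genes at an unadjusted p under 0.05, 1 called by DESeq2, 0 in the 15-library fit, and 1 without WT PBS replicate 2. The 5 genes of smallest p were Zfp760 (0.81 ± 0.15), the predicted genes Gm5165 (0.88 ± 0.18) and Gm37010 (1.68 ± 0.35), Zfp120 (0.56 ± 0.12) and Zfp958 (0.59 ± 0.13), each with adjusted p = 0.961. NRF2 targets showed a median of -0.06 with no member called either way (adjusted p = 0.266 in camera). Primary granule genes of granulocyte precursors had a median of -0.27, with no call of 20 and 1 lower adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). NF-kappaB and cytokine genes had a median of -0.57 (adjusted p = 0.541 with an estimated correlation) and immediate early genes one of -0.77 (adjusted p = 0.472 with an estimated correlation), both with no member called either way. Both lists move with WT PBS replicate 2, the library of high Fos level, without which their medians were -0.15 and -0.17 and their adjusted p-values in camera 0.0858 and 0.111. The smallest adjusted p of any gene in WT was 0.961.

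In KO, BMX-001 was followed by a fall of 1 gene, the immunoglobulin segment Ighv1-15 (-4.80 ± 0.48, adjusted p = 0.00443), which went from 36.7 ± 16.6 to 1.32 ± 0.027 CPM (SD, n = 2 each). Monocyte genes had a median of -0.55 with no call of 24 and 11 lower adjusted over the list alone, neutrophil secondary granule genes -0.47 with 11 of 20 and primary granule genes -0.50 with 8 of 20, each with adjusted p = 0.451 with an estimated correlation. These lists move with KO BMX-001 replicate 1, where Mpo stood at 283.5 CPM against 1495 CPM in replicate 2, and without replicate 1 their medians were -0.34, -0.39 and -0.32. DESeq2 called 1834 genes. In edgeR the count was 8 without KO PBS replicate 1, 3 without KO PBS replicate 2, 9015 without KO BMX-001 replicate 2 and 0 without KO BMX-001 replicate 1, where Ighv1-15 had adjusted p = 0.436. The interaction of genotype with BMX-001 called no gene in edgeR (2119 at an unadjusted p under 0.05, 8 in DESeq2, 0 in the 15-library fit). It called 6402 without KO BMX-001 replicate 2 and 5 without KO PBS replicate 1. Ighv1-15 was nearest in the 16-library fit (-4.88 ± 0.63, adjusted p = 0.0786).

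**Figure D3:**
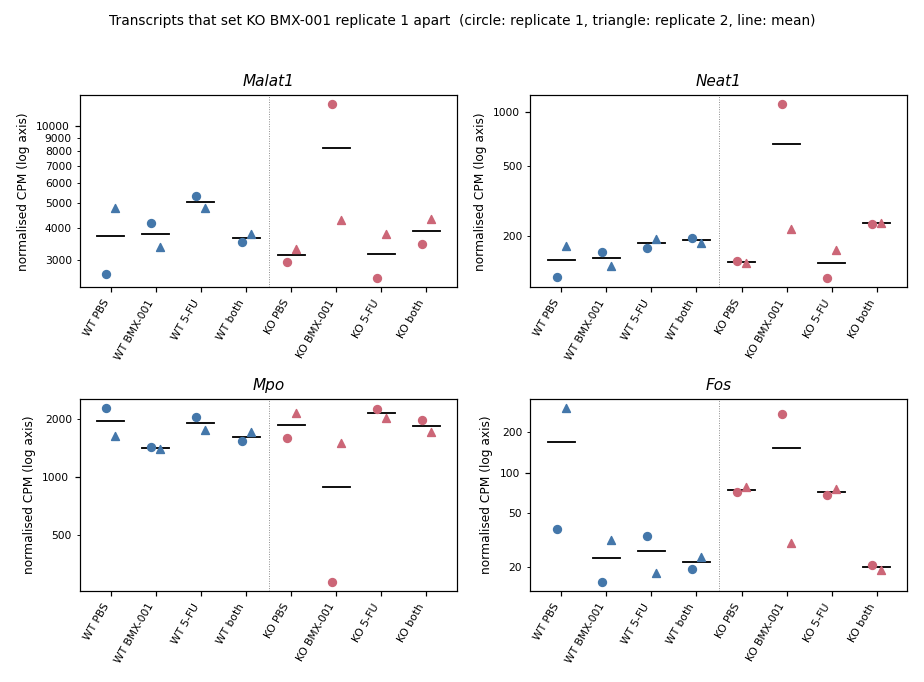
Normalised CPM on a log axis for the nuclear RNAs Malat1 and Neat1, the granule enzyme gene Mpo and the immediate early gene Fos in the 8 groups; circles are replicate 1, triangles replicate 2 and lines the group means, with WT in blue and KO in red. KO BMX-001 replicate 1 reaches 12210 CPM of Malat1 and 1114 CPM of Neat1, and WT PBS replicate 2 reaches 300.6 CPM of Fos.

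The combination was compared with 5-FU alone to ask whether BMX-001 alters the response to the drug. In WT the haemoglobin genes Hba-a1 (0.49 ± 0.16) and Hbb-bs (0.48 ± 0.19) lay higher with BMX-001, each with adjusted p = 0.998. Hba-a1 stood at 10780 ± 758 CPM with both drugs and 7657 ± 592 CPM with 5-FU (SD, n = 2 each). Erythroid genes had a median of 0.11 (28 of 35 positive), other antioxidant genes 0.17 (20 of 22), T and NK cell genes 0.32 (28 of 30) and interferon response genes 0.23 (27 of 32). All 4 lists passed camera with no member called either way, and each had adjusted p = 0.853 with an estimated correlation. No gene passed in edgeR (753 at an unadjusted p under 0.05) or in DESeq2 (0), and 0 in the 15-library fit; leaving out WT BMX-001 with 5-FU replicate 1 gave 3. The 5 genes of smallest p were Zc3h6 (0.85 ± 0.18), Gm42547 (-0.71 ± 0.16), Elof1 (0.36 ± 0.08) and the mitochondrial ribosomal RNAs mt-Rnr2 (-1.30 ± 0.30) and mt-Rnr1 (-1.28 ± 0.30), each with adjusted p = 0.998. Without that library the T and NK cell list had a median of 0.06 (adjusted p = 0.343 in camera) and the interferon list one of 0.05 (adjusted p = 0.568), and without WT 5-FU replicate 2 the interferon list one of 0.07 (adjusted p = 0.122).

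In KO the combination differed from 5-FU alone in no gene in edgeR, with 499 genes at an unadjusted p under 0.05, 6 in DESeq2, 1 without KO 5-FU replicate 1 and 1 in the 15-library fit, Ifi208, an interferon-inducible gene (1.41 ± 0.20, adjusted p = 0.0394). Iglv1 had the smallest p (-1.33 ± 0.26, adjusted p = 1). Erythroid genes had a median of 0.01 with no member called either way and adjusted p = 0.513 in camera. Plasma cell genes had a median of -0.42, with no call of 20 and 1 lower adjusted over the list alone (adjusted p = 0.314 with an estimated correlation), and stromal genes one of -0.51 with no member called either way (adjusted p = 0.437 with an estimated correlation). The interaction of genotype with BMX-001 under 5-FU called no gene in edgeR (891 at an unadjusted p under 0.05, 1 in DESeq2, 0 in the 15-library fit), and 1 without KO 5-FU replicate 2. Its 3 genes of smallest p were the immunoglobulin segment Igkv8-19 (-3.41 ± 0.68), the predicted gene Gm16299 (2.08 ± 0.46) and Elof1 (-0.51 ± 0.12), each with adjusted p = 0.966.

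To test whether BMX-001 shifted the genes that 5-FU lowers without choosing them on the libraries under test, the 85 genes lower after 5-FU in KO were followed in WT marrow. With both drugs against 5-FU alone, 76 of the 85 (89.4%) had a positive log2 fold change, with a median of 0.20. The set passed camera with the preset correlation (p = 1.19e-19) and did not with an estimated correlation (p = 0.0945). In the 15-library fit 69.6% of 473 such genes were positive (p = 0.178 with an estimated correlation). In the other direction, of the genes called lower after 5-FU in WT in the 15-library fit 27.4% moved against the 5-FU effect in KO when BMX-001 was added, and of those called higher 27.9% did. Neither set passed camera with an estimated correlation (p = 0.239 and 0.101). Of these WT calls with a GC value only 11.3% stayed called with GC and length trends removed, so the sets may reflect such trends.

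Both drugs together were last compared with PBS. In KO marrow erythroid genes fell, with Epb42 at -0.82 ± 0.12 on the log2 scale (adjusted p = 0.0148), Tmcc2 at -0.97 ± 0.15 (adjusted p = 0.0222) and Trim10, a regulator of erythroid maturation, at -0.81 ± 0.13 (adjusted p = 0.0222). Of 35 erythroid genes 8 fell, 22 adjusted over the list alone, with a median of -0.45 (adjusted p = 5.87e-30 in camera; adjusted p = 0.147 with an estimated correlation). Slc25a37 fell by 0.75 ± 0.14, Cat by 0.88 ± 0.12, Ucp2 by 0.73 ± 0.14 and the autophagy receptor gene Sqstm1 by 0.62 ± 0.12. The monocyte genes Crip1 (-0.54 ± 0.10) and Ccl9 (-0.71 ± 0.14) were the 2 of 24 that fell, 7 adjusted over the list alone, with adjusted p = 0.147 with an estimated correlation. Rsad2 (-1.09 ± 0.18) was the 1 of 32 interferon response genes that fell, 11 adjusted over the list alone (adjusted p = 0.208 with an estimated correlation). Iglv1 fell by 2.13 ± 0.26 and Ppp1r15a, a regulator of the integrated stress response, by 0.99 ± 0.18, and Inpp4b rose by 0.61 ± 0.11.

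In total 116 genes changed in KO, 6 higher and 110 lower, with 490 in DESeq2, 1054 in the 15-library fit and 1018 with only the 2 groups in the fit. The count was 40 without KO PBS replicate 1 and 1 without KO PBS replicate 2 or either library of the combination. Each named gene but Iglv1, which was lost without KO BMX-001 with 5-FU replicate 1 (adjusted p = 0.219), lost its call without at least 3 of the 4 libraries (adjusted p-values up to 0.492) and kept its sign. Of the 85 genes lower after 5-FU and the 110 lower after both drugs, 73 were shared, where independent lists would share 0.488. Both comparisons use the same PBS libraries, so the lists are not independent. In 20 simulated sets of 15 libraries in which neither treatment changed a gene in KO, the log2 fold changes of these comparisons had a mean correlation of 0.49. The simulated lists shared 0 lower genes in every set. With means of only 0.85 genes called for 5-FU and 0.4 for both drugs, they could hardly share any. They therefore do not show how much of the excess comes from the shared libraries, and this was not tested otherwise.

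In WT no gene passed for both drugs against PBS in edgeR, with 1259 genes at an unadjusted p under 0.05, 22 in DESeq2 and 2 in the 15-library fit, Zfp958 (0.84 ± 0.12) and the p53 target Eda2r (3.26 ± 0.48), each with adjusted p = 0.0359. Eda2r stood at 1.35 ± 0.398 CPM with both drugs and 0.137 ± 0.114 CPM in PBS (SD, n = 2 each). Without WT PBS replicate 2 the 16-library count was 2. Monocyte genes had a median of -0.28 with no member called either way (adjusted p = 0.544 with an estimated correlation), and mature neutrophil genes -0.18, negative in all 26, also with no member called either way (adjusted p = 0.59 with an estimated correlation; adjusted p = 0.127 in camera without WT PBS replicate 2 and 0.0551 without WT BMX-001 with 5-FU replicate 2).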

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

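The tests chosen after the result was seen were that of the spread added by thinning, that of a smaller share of erythroid cells, that of a deviating library behind the 5-FU calls in WT, and all tests on the 15-library fit. In 24 sets of 8 WT or 8 KO libraries, 1 measure each, 8 values lay far from the other libraries of their genotype by Dixon's test. KO BMX-001 replicate 1 held 6 of them: a total of 27305707 counts, 16.66 CPM of Nfe2l2, 12210 CPM of Malat1, 1114 CPM of Neat1, 283.5 CPM of Mpo and 273.4 CPM of Fos. WT PBS replicate 2 held the others, 102.2 CPM of Nfe2l2 and 300.6 CPM of Fos.

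KO BMX-001 replicate 1 spread around the other KO libraries by 0.869 on the log2 scale, against 0.506 for the next widest KO library. Lower depth is argued against as the whole source, since thinning another KO library to its depth added at most 6.7% of the excess spread. The spread of KO BMX-001 replicate 1 was 1.66 times that of the widest thinned library. This ratio lay between the bounds written before the test and so decided nothing. A larger share of unspliced or nuclear RNA is a candidate explanation: the median log2 ratio of 698 sense-intronic and unconfirmed genes was 1.3 in this library and between -0.49 and 0.44 in the other KO libraries. A different mix of marrow cell types stays open, as 2 of 15 cell type lists (macrophages and stem and progenitor cells) lay beyond the range of the other KO libraries by more than that range, and 9 lay outside it.

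The fall of erythroid genes after 5-FU in KO kept its sign without any of the 4 compared libraries, and the list median closest to 0 was -0.36, which argues against a deviating library as its source. A trend with GC content or transcript length is argued against too: with each library's trend removed in the 15-library fit the median kept 110.2% of its size, going from -0.42 to -0.47. A smaller share of erythroid cells may account for it, because haemoglobin genes fell with the other members, with a difference of medians of -0.18 (-0.59 and -0.41). A lower expression of these genes within the cells was not tested and stays open. Medians in WT were -0.65 for haemoglobin genes and -0.09 for the other members.

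The 1353 genes called after 5-FU in WT without KO BMX-001 replicate 1 may reflect differences between libraries in GC content and transcript length. With the test limited to the 18699 genes that have a GC value, 1271 were called, and 11.3% of these stayed called with the trends removed. Their median absolute log2 fold change went from 0.45 to 0.30 with a median SE of 0.10 before and after, so smaller changes rather than larger errors went with the loss of calls. Genes called higher had a median GC content of 41.5% and a length of 4036 bases, and genes called lower 55.2% and 2245 bases. A deviating library may contribute, since the count was 9 without WT 5-FU replicate 2. Whether 5-FU itself changes transcripts by GC content cannot be separated from these trends with 2 libraries per group.

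For the 34 genes called between the genotypes, 1 of 100 splits of the libraries within treatments, the real one, gave as many, and the highest other split gave 13. Called genes were more frequent among the 200 tested genes nearest to Nfe2l2, with 3 called (Tanc1, Mrpl23-ps1 and E030042O20Rik; odds ratio 9.45, Fisher's exact p = 0.00511) and 10 in the 15-library fit, among them Ly75 and Ifih1 (odds ratio 3.76, p = 0.000588). Of the 3, Tanc1 lost its call without any of 11 of the 16 libraries (largest adjusted p 0.115).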

How the results depend on the processing

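The tests chosen after the results were seen were the 15-library fit, that fit with another library left out, and that fit with GC and length trends removed. RLE scaling and the removal of haemoglobin genes kept all 13 counts within 1.5 times, no called named gene changed sign under any setting tried (genes that were not called did), and the Nfe2l2 calls in the 2 genotype comparisons held under each. The count of calls was the least stable quantity. DESeq2 made more calls than edgeR in 12 comparisons, and the cause was not tested. A filter that removes no genes also gave more calls in all 13, and its cause was not tested. The 15-library fit and the leave-out settings change the libraries and so the estimated spread.

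With no filter on low counts the calls numbered 879 for KO against WT over treatments, 268 in PBS, 634 for 5-FU in WT, 737 for 5-FU in KO, 187 for BMX-001 in WT, 3651 for BMX-001 in KO, 36 and 137 for both drugs against 5-FU in WT and KO, 234 and 646 for both drugs against PBS in WT and KO, and 200, 883 and 107 for the interactions with 5-FU, with BMX-001 and with BMX-001 under 5-FU. In the same order DESeq2 gave 347, 36, 474, 379, 1, 1834, 0, 6, 22, 490, 19, 8 and 1, of which the 0 was unchanged. With only the compared groups in the fit the counts that moved were 0 for 5-FU in WT, 200 for 5-FU in KO, 0 for BMX-001 in KO, 1 and 5 for both drugs against 5-FU in WT and KO, 1 and 1018 for both drugs against PBS in WT and KO, and 1 for each of the interactions with 5-FU and with BMX-001 under 5-FU. In the 15-library fit those that moved were 273 for KO against WT over treatments, 20 in PBS, 1353 for 5-FU in WT, 556 for 5-FU in KO, 0 for BMX-001 in KO, 1 for both drugs against 5-FU in KO, and 2 and 1054 for both drugs against PBS in WT and KO. With GC and length trends also removed they were 339 for KO against WT over treatments, 20 in PBS, 199 for 5-FU in WT, 624 for 5-FU in KO, 0 for BMX-001 in KO, 1 for both drugs against 5-FU in KO and 1053 for both drugs against PBS in KO.

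The replicate block gave 0 calls for 5-FU in WT, kept the other 12 counts within 1.5 times (30 for KO against WT over treatments), and moved the median of the 5-FU genes followed in WT to 0.202 from 0.197. Residuals of equal replicate numbers had a median correlation of 0.01 over 28 pairs of groups, from -0.39 to 0.2, with 6 pairs above 0.1. This gave no sign that replicate numbers pair the samples throughout. With 2 libraries per group it cannot exclude a batch shared by some groups.

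A group that loses a library is left with a lone library, which the fit assumes to vary like the others. The range given here covers each compared library alone and together with KO BMX-001 replicate 1. It was 14 to 4467 for KO against WT over treatments (lowest without WT PBS replicate 2, highest without KO BMX-001 replicate 2), 3 to 283 in PBS, 0 to 1612 for 5-FU in WT, 0 to 535 for 5-FU in KO, 0 to 371 for BMX-001 in WT, and 0 to 9015 for BMX-001 in KO (lowest without its replicate 1, highest without its replicate 2). For both drugs it was 0 to 3 in WT and 0 to 7 in KO against 5-FU, and 0 to 492 in WT and 1 to 563 in KO against PBS. For the interactions it was 0 to 135 with 5-FU, 0 to 6402 with BMX-001 and 0 to 9 with BMX-001 under 5-FU. The values of 283, 1612, 371, 492 and 135 all left out WT PBS replicate 1 together with KO BMX-001 replicate 1. Of 13 named genes called for KO against WT over treatments 8 stayed called in each leave-out, of 5 in PBS 1, and none of the 13 for 5-FU in KO or the 17 for both drugs against PBS in KO did. The median of the 5-FU genes followed in WT was 0.149 to 0.273, and 0.081 in the 15-library fit. Leaving out KO PBS replicate 2 or either KO 5-FU library left too few genes to follow, so it gave no value.

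With an estimated correlation none of the list calls held. It ended 193 of them, including that of the 5-FU genes followed in WT, whose median of 0.197 is the same by construction (camera p = 0.0945 with the estimated correlation). Leaving out a library turned the direction in camera, which ranks all genes and can differ from the sign of the median, for 31 of 351 combinations of list and comparison. The ranges of their medians over the left-out libraries follow, with the value from all 16 libraries in brackets. For KO against WT over treatments the medians ran from 0.004 to 0.27 for NF-kappaB genes (0.18). For KO against WT in PBS the medians ran from -0.17 to 0.17 for dendritic cell genes (0.036), -0.78 to 0.86 for megakaryocyte genes (-0.18), -0.54 to 0.067 for NF-kappaB genes (-0.32) and -0.76 to 0.145 for immediate early genes (-0.57). For BMX-001 in WT the medians ran from 0.005 to 1.63 for megakaryocyte genes (0.57) and -0.27 to 0.39 for stromal genes (0.031). For both drugs against PBS in WT the medians ran from -0.12 to 0.009 for erythroid genes (-0.039), -0.055 to 0.51 for T and NK cell genes (0.23), -0.064 to 1.78 for megakaryocyte genes (0.50) and -0.20 to 0.20 for interferon response genes (0.046). For the interaction with 5-FU the medians ran from -0.88 to 0.77 for megakaryocyte genes (0.15). For the interaction with BMX-001 the medians ran from -0.24 to 0.13 for mature neutrophil genes (-0.094), -1.95 to 0.25 for megakaryocyte genes (-0.49) and -0.87 to 0.81 for stromal genes (-0.15). For the interaction with BMX-001 under 5-FU the medians ran from -0.28 to 0.035 for cell cycle genes (-0.11) and -0.65 to 0.042 for B cell precursor genes (-0.265). For 5-FU in KO the medians ran from -0.27 to 0.26 for B lineage genes (-0.03). For BMX-001 in KO the medians ran from -1.01 to 0.10 for macrophage genes (-0.26), -1.245 to 0.87 for megakaryocyte genes (0.10), -0.825 to 0.88 for stromal genes (-0.078), -0.16 to 0.88 for NF-kappaB genes (0.495) and -0.24 to 0.79 for immediate early genes (0.38). For both drugs against PBS in KO the medians ran from -0.30 to 0.13 for B lineage genes (-0.11) and 0.038 to 1.32 for stromal genes (0.40). For both drugs against 5-FU in KO the medians ran from -0.17 to 0.034 for NRF2 targets (-0.084), -0.21 to 0.091 for cell cycle genes (-0.066), -0.13 to 0.095 for heme and iron genes (-0.021), -0.25 to 0.005 for monocyte genes (-0.11), -0.44 to 0.29 for B cell precursor genes (-0.037) and -0.29 to 0.13 for interferon response genes (-0.064). Leave-outs that ended a call without turning it numbered 211 for lists and 172 for named genes, against 1690 and 2631 without a change.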

Other observations

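Tests described here on the 15-library fit were chosen after the data were seen. Several marrow groups that the comparisons did not bring up also leaned one way in KO marrow over the 4 treatments. Neutrophil secondary granule genes had a median log2 fold change of 0.12, with 19 of 20 positive, no member called and 4 higher adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). In the 15-library fit Ifitm6 (0.32 ± 0.06) and Abca13 (0.26 ± 0.06), genes of maturing neutrophils, were called higher. Mature neutrophil genes had a median of 0.16 (0.096 without KO BMX-001 replicate 1), with no member called either way (adjusted p = 0.404 with an estimated correlation), and dendritic cell genes one of 0.12 with 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.404 with an estimated correlation). The dendritic list no longer passed camera without KO PBS replicate 1 (median 0.076, adjusted p = 0.0613) or KO BMX-001 replicate 2 (adjusted p = 0.0735). Interferon response genes had a median of -0.20, with 5 of 32 lower adjusted over the list alone (adjusted p = 0.373 with an estimated correlation), and Ifih1, a sensor of viral RNA, was called lower in the 15-library fit (-0.29 ± 0.07, adjusted p = 0.0437). Ifih1 is among the 200 tested genes nearest to Nfe2l2, where called genes were more frequent. Genes of ATF4 and the unfolded protein response had a median of -0.15, with 2 of 28 lower adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). In DNA repair the median was -0.03 (-0.015 without KO BMX-001 replicate 1), with 4 of 29 lower adjusted over the list alone (adjusted p = 0.404 with an estimated correlation).

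Pyrimidine and thymidylate genes, the pathway that 5-FU blocks, gave no member called and none adjusted over the list alone after 5-FU, with a median of 0.01 in WT (adjusted p = 0.662 in camera) and 0.08 in KO (adjusted p = 0.36 in camera). Cell cycle genes had medians of -0.04 in WT (adjusted p = 0.662 in camera) and -0.07 in KO (adjusted p = 0.0752 in camera) after 5-FU, also with no member called either way. The p53 targets Cdkn1a and Eda2r were read by library. Cdkn1a stood at 33.04 and 24.39 CPM in the KO 5-FU libraries and at 8.961 and 10.98 CPM in the KO PBS libraries, and was not called (adjusted p = 0.19). In WT it stood at 14.76 and 15.82 CPM after 5-FU and at 8.605 and 20.41 CPM in PBS, so no rise held across the WT libraries. Eda2r stood at 0.0334 to 0.393 CPM in the 8 libraries without 5-FU and at 0.677 to 1.82 CPM in the 8 with it. The list of p53 targets was set before the data were read, and these 2 members were picked from it afterwards.

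Igha was picked for a reading by group after its values were seen. It stood at 1852 ± 488 CPM in KO PBS, 468 ± 367 CPM in KO BMX-001, 693 ± 253 CPM in KO 5-FU and 711 ± 217 CPM in KO with both drugs (SD, n = 2 each), and at 89.9 ± 24.3 CPM in WT PBS. It was thus higher in every KO group than in WT PBS, and its fall with BMX-001 in KO was not called (adjusted p = 0.088).

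Across all 19152 genes the effects of adding BMX-001 to 5-FU in WT and in KO had a Pearson correlation of -0.14 and a Spearman correlation of -0.17, while those of 5-FU alone had 0.23 and 0.32; the 2 effects of each pair share no library, and genes are not independent replicates.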
